A study of Mus musculus with 28 samples.

How the data were processed

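CUT&Tag coverage of H3K27ac and H2BK120ac was compared between groups of mouse embryonic stem cell samples. Per the labels, H3K27ac in asynchronous cells had 2 EtOH and 2 4HT samples, and H2BK120ac had 3 samples in each of the groups coded ED, ET, TD and TT. The meaning of these codes is not given in the sources used here. The 12 samples sorted by cell cycle phase were not analysed here.

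The deposited values are coverage signal in 127646 regions, given as CPM in the names of the tables. The authors merged the replicates, so that each group has 1 column. The median region width was 252 bp (range 112 to 3246 bp). The submitters' processing notes name the mm10 build for all samples, and featureCounts and DESeq2, without a role, for the H3K27ac samples. The aligner and the coverage tool are not given in the sources used here. The names of the tables carry ATAC, an assay of open chromatin, beside CPM, but the rule that set the regions is not stated. A region without coverage holds no number, no value is 0, and no value lies below that of a single fragment or, in H2BK120ac, 0.25 of it. Bases without coverage were therefore left out of a region's mean, which raises the values of sparsely covered regions. Between 23.1% (H3K27ac EtOH) and 48.2% (TD) of the regions had no coverage. A missing value was counted as 0. The tables of the marks were analysed apart. A further 16 value columns, 8 in each of 2 tables, carry IgG in their names, match no sample and were not used. How far background shapes the H2BK120ac profiles, such as the flat profile of ED and ET around TSS, was therefore not examined. From one of those tables the positions of 38087 windows around transcription start sites (TSS), each 5 kb wide, were taken as coordinates.

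The commonest value of a column was read as the value of 1 fragment: 0.445 for ED, 0.445 for ET, 0.412 for TD, 0.415 for TT, 0.165 for H3K27ac EtOH and 0.207 for H3K27ac 4HT. Its inverse gives the implied depth. At these depths most regions rest on 1 or a few fragments, and 2377 regions in ED, 2833 in ET, 4529 in TD, 3935 in TT, 14487 in H3K27ac EtOH and 13720 in H3K27ac 4HT reached a pile-up of 5 fragments. Counting intervals are exact 95% Clopper-Pearson intervals on the share of pile-up between the columns compared, turned into ratios. They cover counting error only, and a pile-up understates the fragments that touch a region.

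The comparisons and the gene lists were fixed before the data were examined. The planned limma fits, camera and fry tests and the exact permutation tests need separate replicates and could not be run on 1 merged column per group, so no p-value is given. In their place, folds were taken on log2(value + pseudocount), which understates the change of low regions. The pseudocount was the 25th percentile of the positive values to 1 significant digit, 0.4 for H2BK120ac and 0.2 for H3K27ac. Regions were kept where the mean over the groups of a table reached the pseudocount, 44136 for H2BK120ac and 65565 for H3K27ac. After the tables were seen to be merged, a size rule was set: at least 2-fold in regions whose mean pile-up reached 5 fragments, called well covered (2782 regions at 2.15 or more for H2BK120ac, 13807 at 0.93 or more for H3K27ac). Counting noise was simulated 100 times by drawing the pile-up of both columns from a Poisson distribution with their mean rate.

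Regions were named after the protein-coding gene with the nearest TSS, with RefSeq gene spans on GRCm38.p6. These give no strand, exons or untranslated regions, so only overlap with a gene span is reported. A gene's TSS was the end of its span nearest to the anchor of a deposited TSS window, within 5 kb, which held for 20494 of 21887 genes and lay within 100 bp for 14810. Regions within 1 kb of a TSS were called proximal and the rest distal. A gene's value was the mean over its kept regions within 50 kb. List medians were set against 10000 random lists matched on decile of mean signal, and the percentile describes these columns only. The 18 lists held 187 genes. The text names, per comparison, members of the 10 regions with the largest log2 fold in each direction among well-covered regions with coverage in both groups. For listed genes it names the promoter and the distal region of highest mean signal, and it gives Foxd3 in every group. The first part of this rule replaces a planned one that needed adjusted p-values. The naming of regions of opposite direction, the plotted lists and loci, and gene values quoted beside the named regions were chosen after their values were seen.

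The size rule was tested on simulated pile-ups in which some regions were changed by known folds. For TD against ED it found 82.4% of 91 regions changed 4-fold and 37.9% of 87 changed 2-fold, with 14.9% of unchanged regions passing, among 3001 regions. For H3K27ac it found 88.9% of 99 and 44.4% of 90, with 11.0% of unchanged regions passing, among 14697 regions. These simulations draw the same Poisson noise as above, which appears larger than that in the data. In TT against TD 14.4% of unchanged simulated regions passed. In the data 2.48% of the well-covered regions were higher and 5.75% lower in that comparison. A simulated list of genes changed 2-fold in TD against ED, 193 of them measured among 12341 genes, had a median log2 fold of 0.81 at percentile 100, and an unchanged list -0.03 at percentile 72.5. These lists were enlarged after a smaller one had given an imprecise median. The fixed lists are far smaller, and their random lists spread more widely. For the 10 measured p53 target genes in TD against ED, the central range of matched random lists was 0.06 to 1.95. A median of 0.81 lies inside that range. The simulation therefore does not show whether a fixed list changed 2-fold would stand out by its percentile. Alternatives were other pseudocounts, filters, scalings and distances, other pile-up minimums, and H2BK120ac regions chosen by H3K27ac coverage. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.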

Results

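The samples came from mouse embryonic stem cells (mESCs) that carry an inducible knockout of FOXD3, a forkhead transcription factor of pluripotent cells. The study depleted FOXD3 with 4-hydroxytamoxifen (4HT) and set those cells against solvent-treated cells, with a treatment time of 24 h in the labels and L2i as the culture medium. Active chromatin was profiled by CUT&Tag, in which an antibody directs a transposase to the chromatin that carries a mark. H3K27ac is an acetylated lysine of histone H3, found at active promoters and enhancers. H2BK120ac is an acetylated lysine of histone H2B, another mark of active chromatin.

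There were 28 samples. H3K27ac in asynchronous cells had 2 solvent (EtOH) and 2 4HT samples. H2BK120ac had 12 samples, 3 in each of 4 groups that the titles code as ED, ET, TD and TT. The labels do not spell these codes out, so the groups keep their codes, and whether either letter marks FOXD3 depletion is not known here. TD against ED or TT against ET changes the first letter with the second held. A further 12 samples sorted by cell cycle phase were not analysed here. The values were depth-normalized coverage (CPM) in 127646 regions of the mm10 genome build (GRCm38), with 1 column per group in which the replicates had been merged. No replicate spread could therefore be computed, no test was run, and each region's coverage below is the merged value of the authors, from which the folds, gene means, medians and correlations were computed. Regions were compared by size, at least 2-fold on the log2(value + pseudocount) scale, and intervals on ratios cover counting error only. The commonest value of each column, read as that of 1 fragment, implied depths of 2.25 M fragments for ED, 2.25 M for ET, 2.43 M for TD and 2.41 M for TT. For H3K27ac it implied 6.08 M for EtOH and 4.82 M for 4HT. The lowest H2BK120ac values were 0.25 of the commonest, so the H2BK120ac depths, pile-ups and counting intervals rest on that reading.

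Foxd3 (chromosome 4, 99656299 to 99658671) was examined first, as the targeted gene. Only 2 regions lay inside the gene, and their coverage was that of 2 fragments or fewer. In H3K27ac the region at 99657277 to 99657563 had 0.224 and the one at 99657631 to 99658063 had 0.165 in EtOH, and neither had coverage in 4HT. In H2BK120ac the same regions had coverage in TD alone, at 0.103 and 0.807. This depth did not allow the labels to be checked on the gene itself. Around Foxd3, H3K27ac values were higher in 4HT than in EtOH, except at 99661148 to 99661376 (0.259 against 0.296). At 99626224 to 99626345 both were the value of 1 fragment (0.207 against 0.165), so that difference is depth scaling alone. The values at 99627113 to 99627427 (0.255 against 0.203) were also near 1 fragment. The region at 99626598 to 99626747 had no H3K27ac coverage in either group. The region 241 bp from its transcription start site (TSS), at 99655987 to 99656129, had 2.81 against 1.02, a ratio of 2.76 (95% counting interval 1.06 to 9.33). The strongest Foxd3-assigned region more than 1 kb from the TSS, at 99670116 to 99670739, had 7.02 against 3.03, a ratio of 2.32 (1.31 to 4.48). Over its kept regions the Foxd3 mean was 2.77 in 4HT and 1.46 in EtOH, a log2 fold of 0.84 at percentile 95.3 of genes of like signal, and 0.50 after quantile normalization. In H2BK120ac the mean was 1.22 in ED, 1.84 in ET, 0.817 in TD and 1.16 in TT, and the log2 fold was -0.42 in TD against ED and -0.52 in TT against ET.

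H3K27ac in 4HT against EtOH addressed the effect of FOXD3 depletion on active promoters and enhancers. Values were higher in 4HT at strongly marked regions in general. Of 13807 well-covered regions, 1060 were at least 2-fold higher and 102 at least 2-fold lower, with a median log2 fold of 0.33. Counting noise alone, simulated with equal rates, gave 741 higher and 891 lower on average. The split between the directions was 835 higher and 137 lower after median centring, and 423 higher and 294 lower after quantile normalization, which gives both columns one distribution. The median log2 fold was 0.19 at regions with a mean value of 0.5 to 1, 0.38 at 2 to 4 and 0.43 at 8 or more. Over all kept regions the median was 0.13. Median centring sets the medians of both columns equal, which is not the same as removing this median fold.

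Naive and general pluripotency genes followed this general difference. None of 18 naive pluripotency genes was 2-fold higher or lower, 15 had a positive log2 fold, and the list median of 0.36 lay at percentile 84.8 of matched random lists. The distal region of Klf2, a naive pluripotency factor, at chromosome 8, 72333563 to 72334150, had 13.7 in 4HT against 8.92 in EtOH (ratio 1.53, 1.06 to 2.25). The distal region of Tfcp2l1, another naive factor, at chromosome 1, 118647912 to 118648407, had 11.2 against 6.68 (ratio 1.68, 1.09 to 2.55). The region 1904 bp from the TSS of Pou5f1, which encodes OCT4, at chromosome 17, 35503875 to 35504382, had 16.7 against 14.9 (ratio 1.12, 0.82 to 1.53). For Tdgf1, the gene of the Nodal co-receptor Cripto, the promoter region at chromosome 9, 110946515 to 110947011, had 5.94 against 2.58 (ratio 2.31, 1.20 to 4.50). Suz12, a subunit of Polycomb repressive complex 2, is on the list of chromatin regulators instead. Its distal region at chromosome 11, 79980572 to 79980898, had 7.25 against 3.08 (ratio 2.35, 1.29 to 4.29).

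The formative and primed pluripotency list was the lowest against its random lists, with a median of -0.17 at percentile 2.02. Of its 11 measured genes, 3 had a positive log2 fold and none reached 2-fold in either direction. Pou3f1, a factor of the formative state, had 0.207 in 4HT and 0.325 in EtOH, and Cdh2, Fgf15 and Fgf5 had the same 0.207 in 4HT, the value of a single fragment. Members with more coverage went both ways, with 1.02 against 0.768 for Otx2, 1.49 against 1.10 for Zic5 and 0.619 against 0.729 for Zic2. The low list median therefore rests in part on genes at the level of 1 fragment. The p53 target list had a median of 0.45 at percentile 95.2, and 1 of 10 genes passed 2-fold, the nuclease gene Aen (log2 fold 1.35). After quantile normalization the p53 target median was 0.19. The p53 list and each list named next lay inside the central 95% of their random lists. Their medians were 0.40 for housekeeping genes, 0.33 for general pluripotency, 0.33 for chromatin regulators, 0.32 for germline, 0.28 for FGF-ERK targets, 0.26 for immediate early genes, 0.23 for primitive endoderm and 0.23 for fibroblast feeder markers. They were 0.20 for WNT targets, 0.18 for cell cycle, 0.17 for the Fox and Sox family, 0.12 for mesendoderm, 0.12 for trophectoderm and -0.04 for neuroectoderm. Quantile normalization turned the cell cycle (-0.05), Fox and Sox (-0.05) and mesendoderm (-0.11) medians negative. Among 14305 genes with a kept region, 301 were at least 2-fold higher and 135 at least 2-fold lower.

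Among well-covered regions with coverage in both groups, those with the largest H3K27ac differences rested on few fragments in the lower group. The largest higher value lay 14012 bp from the TSS of Rps20, a ribosomal protein gene, at chromosome 4, 3821560 to 3821727, with 3.06 in 4HT against 0.170 in EtOH (ratio 18.0, 2.91 to 796). Next were regions near Pja2 (3.22 against 0.336), Tgif1 (3.36 against 0.398), Gtf2a1 (2.43 against 0.282) and Mroh6 (1.85 against 0.178). The largest lower values lay near Gm38457 (0.368 against 1.81) and inside Tnfsf12 (0.338 against 1.70). The ratio at Gm38457 was 0.203 with an interval of 0.0247 to 1.05, which includes 1.

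H2BK120ac in TD against ED showed a difference at the targets of p53, the stress-responsive tumour suppressor. Of 10 measured p53 target genes, 9 were at least 2-fold higher in TD and none was lower, with a list median log2 fold of 2.28 at percentile 99.8 of matched random lists. The region 12 bp from the TSS of Ccng1, which encodes cyclin G1, at chromosome 11, 40754734 to 40755860, had 27.1 in TD against 2.12 in ED (ratio 12.8, 4.98 to 38.8). Inside Cdkn1a, the gene of the cell cycle inhibitor p21, the region at chromosome 17, 29093528 to 29093872 had 15.9 against 0.596 (ratio 26.8, 6.10 to 1461). The Mdm2 region at chromosome 10, 117709943 to 117710493, within the gene of the p53 ubiquitin ligase and 540 bp from its TSS, had 11.3 against 0.445 (ratio 25.5, 4.28 to 1059). Bbc3, which encodes the apoptosis effector PUMA, had 19.8 against 1.56 in a region inside the gene at chromosome 7, 16309245 to 16309710 (ratio 12.7, 4.06 to 42.4). Sesn2 (8.01 against 0.445) and Phlda3 (7.84 against 0.490) had the same direction in their promoter regions. Trp53i11 was the member below 2-fold, with a gene log2 fold of 0.28.

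**Figure D1:**
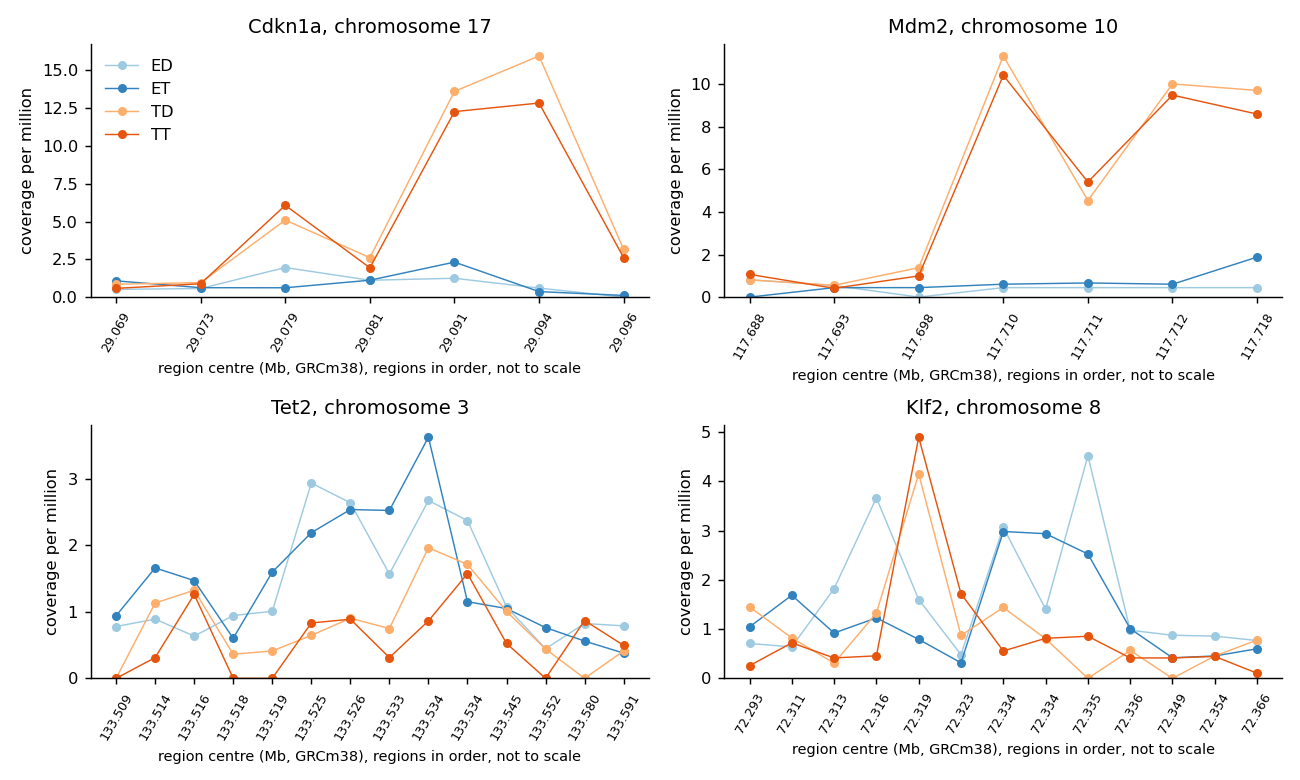
Coverage in CPM (vertical axis) in ED, ET, TD and TT at the kept regions assigned to Cdkn1a, Mdm2, Tet2 and Klf2, in chromosomal order and not to scale (horizontal axis, region centre); a region without coverage is drawn at 0. TD and TT reach 15.9 and 12.8 at Cdkn1a and 11.3 and 10.4 at Mdm2, where ED and ET stay at 2.31 or below.

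Genes of other lists differed in both directions. Over all 11800 genes with a kept region, 17.9% were at least 2-fold higher in TD and 7.96% lower. Of 10 immediate early genes 3 were at least 2-fold higher, with a list median of 0.41 at percentile 48.0. Junb, an AP-1 subunit, had 14.0 in TD against 0.404 in ED in the promoter region at chromosome 8, 84978722 to 84978968 (ratio 34.5, 5.28 to 1278). Of 14 cell cycle genes 5 were higher and 1 was lower, and the list median of 0.64 lay at percentile 98.9. In TT against ET the same list had a median of 0.54 at percentile 97.3, inside the central 95%, and in ET against ED 0.30 at percentile 97.0. Mcm5, a subunit of the replicative helicase, had a log2 fold of 2.30, while Ccnd2, the cyclin D2 gene, had -1.77 on 1 kept region without coverage in TD. Among the higher genes, E2f1 and Plk1 each had 1 kept region without coverage in ED, and Plk1 had 0.412 in TD, the value of 1 fragment. Both also passed 2-fold in ET against ED, with log2 folds of 1.10 and 1.08. Housekeeping genes had a median of 0.88 at percentile 96.1, inside the central 95%. In the naive pluripotency list 3 of 18 genes were at least 2-fold higher, none lower, and the median was 0.10 at percentile 10.4. These were Klf4 (2.22 against 0.255), Stat3 (2.98 against 0.445) and Socs3 (log2 fold 1.05), whereas Prdm14 had a log2 fold of -0.87, Tcl1 -0.76, Nr0b1 -0.73 and Tet2 -0.60. After quantile normalization the list median was -0.04. At Prdm14 the distal region at chromosome 1, 13084639 to 13085602, had 0.747 in TD against 3.10 in ED (ratio 0.241, 0.0268 to 1.39). Sox2 had a gene value of 2.36 against 0.534, and its region at chromosome 3, 34653947 to 34654171, had 6.36 against 0.445 (ratio 14.3, 2.13 to 584). The remaining lists lay inside the central 95% of their random lists. Their medians were 0.42 for the Fox and Sox family, 0.41 for chromatin regulators, 0.41 for general pluripotency, 0.31 for FGF-ERK targets, 0.24 for germline and 0.15 for fibroblast feeder markers. They were -0.04 for WNT targets, -0.05 for mesendoderm, -0.05 for formative and primed, -0.06 for neuroectoderm, -0.13 for trophectoderm and -0.15 for primitive endoderm. Median centring turned the WNT (0.03), mesendoderm (0.02), formative and primed (0.02) and neuroectoderm (0.01) medians positive.

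**Figure D2:**
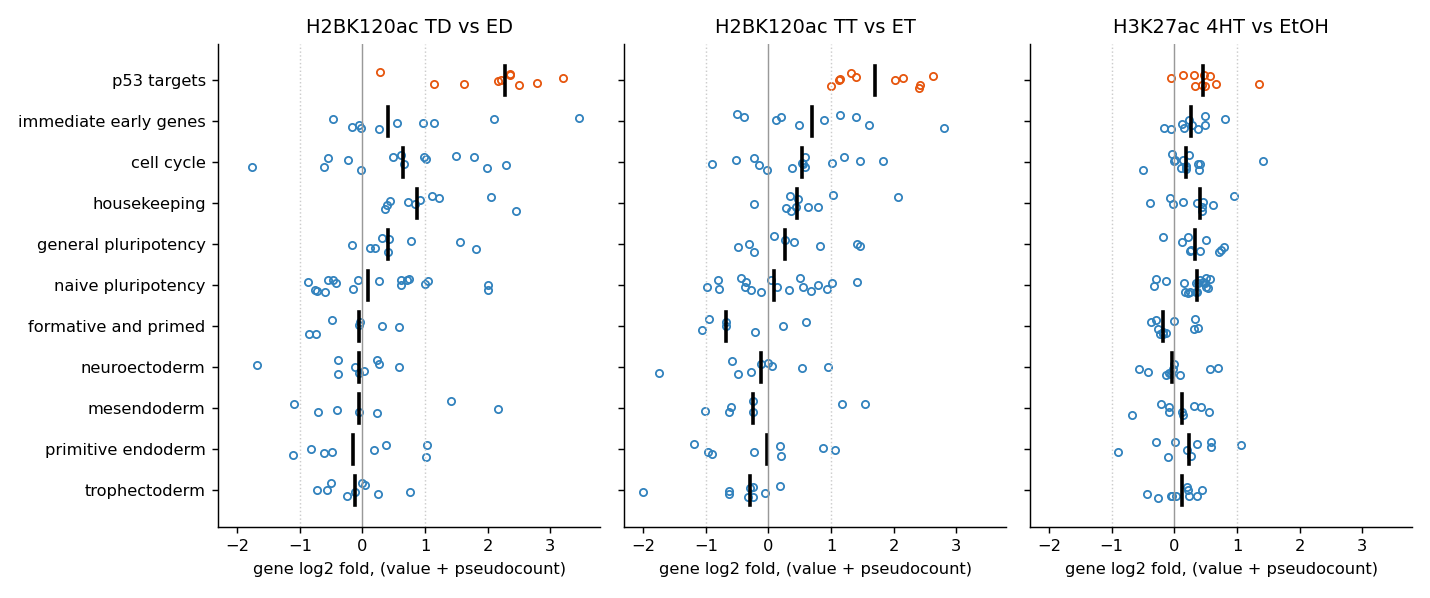
Gene log2 folds of value plus pseudocount (horizontal axis) for the members of 11 lists (rows), with 1 circle per gene, the list median as a bar and dotted lines at 2-fold. The p53 target medians are 2.28 in TD against ED, 1.71 in TT against ET and 0.45 in H3K27ac 4HT against EtOH, the last 0.19 after quantile normalization.

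At well-covered regions TD differed from ED by more than simulated counting noise, and the more frequent direction depended on which regions were counted. Of 2782 well-covered regions, 1533 were at least 2-fold higher in TD and 514 at least 2-fold lower, against 227 and 211 from simulated counting noise. The counts were 3154 higher and 1534 lower with a minimum of 3 fragments, and 8163 and 8048 over all kept regions. Lower values were the more frequent above the median region (11625 higher, 14348 lower), with no filter (19514 and 28137) and at the 13807 regions well covered in H3K27ac (2795 and 2902). No counting noise was simulated for these sets, in which 1 fragment in either group against none in the other already passes 2-fold. TD lacked coverage in 48.2% of all regions and ED in 38.7%. Regions without coverage in either of the compared groups were left out of the ranking that follows. Among the remaining well-covered regions, the largest higher value lay 38591 bp from the TSS of Gpr157. This region, at chromosome 4, 150048557 to 150049268, lay outside annotated protein-coding genes. It had 34.7 in TD and 29.8 in TT, against 0.587 in ED and 1.58 in ET. The region inside Traf4, 109 bp from its TSS, at chromosome 11, 78165408 to 78165968, had 15.6 against 0.111 in ED, which is less than 1 fragment. Near Nfatc2, a region inside Atp9a at chromosome 2, 168669901 to 168670198, had 25.5 against 0.436. Other regions among the 10 with the largest higher values lay inside Ier2 (14.4 against 0.111), Arhgef33 (18.6 against 0.334), Ctc1 (13.2 against 0.169) and Camsap3 (20.2 against 0.513). In the same ranking, the 10 largest lower values all lay at least 18755 bp from the nearest TSS. The largest, 370989 bp from the TSS of Plekhb2 at chromosome 1, 35220796 to 35221101, had 0.379 in TD against 11.8 in ED. Inside C7, a complement gene, the region at chromosome 15, 5023496 to 5023870, had 0.358 against 7.95, and the region near Manea had 0.580 against 8.68.

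H2BK120ac in TT against ET changes the same letter with T as the second. Over all genes, 15.7% were at least 2-fold higher in TT and 8.31% lower. Of 10 p53 target genes, 9 were at least 2-fold higher in TT, and the median of 1.71 lay at percentile 98.4. Trp53inp1 was the member just below 2-fold, and it had 2.32 in TT against 0.959 in ET. Ccng1 had 21.0 against 3.28, the Cdkn1a region inside the gene 12.8 against 0.364, and Mdm2 10.4 against 0.607. Of 10 immediate early genes 4 were higher, with a median of 0.69 at percentile 84.0, and Junb had 8.57 against 0.537 in its promoter region. The formative and primed list lay lowest, with a median of -0.68 at percentile 1.04 and 1 of 7 genes, Lef1, lower by at least 2-fold (0.276 against 1.02). In TD against ED the same list lay at percentile 44.2, and the difference between the comparisons was not tested. Among 2782 well-covered regions, 1379 were at least 2-fold higher and 600 at least 2-fold lower, against 229 and 217 from counting noise. Lower values were the more frequent above the median region (10764 higher, 15068 lower), with no filter (18922 and 28642) and at the regions well covered in H3K27ac (2386 and 3328). These sets again count 1 fragment against none as past 2-fold and had no simulated noise. TT lacked coverage in 47.5% of all regions and ET in 38.7%. The regions named next were ranked among well-covered regions with coverage in both groups. Outside the p53 list the largest higher values included a region inside Ranbp3 near Vmac, at chromosome 17, 56709777 to 56710007 (37.4 against 1.06), and regions inside Arhgef33 (14.2 against 0.171) and Agap1 (20.1 against 0.695). Of the 10 largest lower values, the one inside Hs3st5 (0.434 against 7.43) was the only one within an annotated gene. The rest included regions nearest to Cntnap5b (0.348 against 10.8), Clec14a (0.104 against 5.93), Tecrl (0.726 against 12.2) and Cdh19 (0.207 against 6.19).

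The first-letter differences were alike for both second letters. Across the 2782 well-covered regions the log2 folds of TD against ED and of TT against ET had a Spearman correlation of 0.89, and across the 44136 kept regions 0.57. Regions are not independent replicates, so no p-value is attached. These comparisons share no libraries. At least 2-fold higher in both were 1292 regions, where independent lists would share 760, and 433 were lower in both, against 111. Among the 1731 regions past 2-fold in both, 6 had opposite directions.

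**Figure D3:**
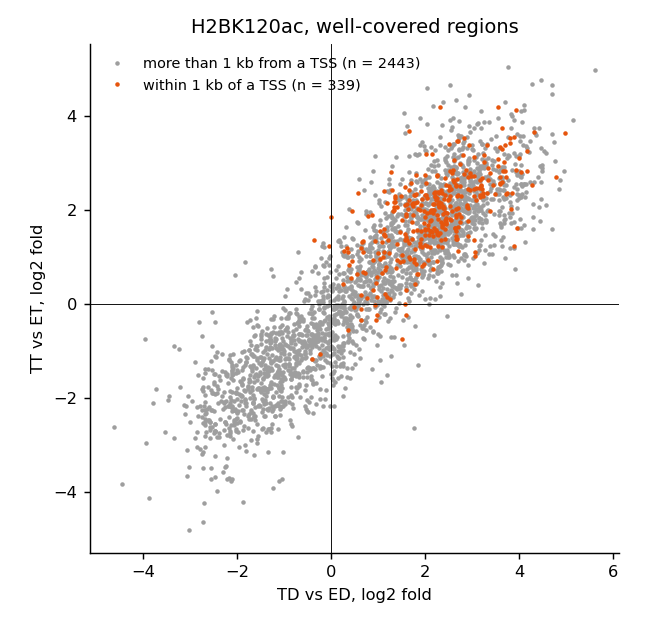
Log2 folds of TD against ED (horizontal axis) and TT against ET (vertical axis) at 2782 well-covered H2BK120ac regions, with the 339 regions within 1 kb of a TSS in orange. The points follow 1 diagonal band (Spearman correlation 0.89), and the TSS-proximal regions sit almost wholly in the upper right.

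In both comparisons of the second letter fewer well-covered regions passed 2-fold than in simulated counting noise. That simulation overstates the noise, so this does not show that the second letter made no difference. In ET against ED 289 well-covered regions were at least 2-fold higher and 107 lower, where counting noise gave 413 and 414. In TT against TD 69 were higher and 160 lower, against 233 and 196 from counting noise. After quantile normalization the TT against TD counts were 61 and 67. The p53 target medians were 0.14 (percentile 56.5) in ET against ED and -0.09 (percentile 57.6) in TT against TD, the latter 0.04 after quantile normalization. Single regions with larger values included one inside Hmgxb4, 7122 bp from the TSS of Tom1, at chromosome 8, 75026455 to 75026586, with 6.25 in ET against 0.624 in ED and 0.675 in TT against 3.07 in TD. A region near Klf13 had 1.02 in ET against 5.22 in ED (ratio 0.195, 0.0181 to 0.749). A Bbc3 region at chromosome 7, 16313581 to 16313751, had 7.09 in TT against 1.82 in TD (ratio 3.89, 1.40 to 17.5). A region near Bambi, the gene of a TGF-beta pseudoreceptor, had 0.802 in TT against 4.77 in TD (ratio 0.168, 0.0183 to 0.754). The interaction, the difference between the first-letter folds, passed 2-fold upward in 137 regions and downward in 576, with a median of -0.36. Counting noise gave 523 and 518 on average, with at most 565 lower. The 576 lower regions exceeded this in the values as deposited. The counts were 157 higher and 522 lower after median centring, and 241 and 410 after quantile normalization. No counting noise was simulated under those scalings, so whether these counts exceed it is not known.

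Promoters and distal regions differed in the first-letter comparisons. Of 339 well-covered regions within 1 kb of a TSS, 300 were at least 2-fold higher in TD than in ED and none was lower. Of 2443 regions farther away, 1233 were higher and 514 lower. In TT against ET the proximal counts were 288 and 2, and the distal counts 1091 and 598. TSS-proximal regions were rare among the highest regions of ED and ET, so few could be well covered without signal in TD or TT, and these counts depend on that filter. At regions chosen by H3K27ac coverage alone, 1120 of 3117 proximal regions were higher in TD than in ED and 83 lower, and of 10690 distal regions 1675 were higher and 2819 lower. For TT against ET these counts were 997 and 97 proximal, and 1389 and 3231 distal. Over the kept regions the TD against ED median was 0.31 for proximal and -0.10 for distal regions, and for TT against ET 0.30 and -0.20. With no filter they were 0.07 and -0.06, and 0.11 and -0.05. Mean coverage within 500 bp of a TSS was 0.448 in ED, 0.453 in ET, 0.740 in TD and 0.720 in TT. Beyond 50 kb it was 0.431, 0.449, 0.328 and 0.306. Among the 1000 regions of highest coverage, 5 were TSS-proximal in ED, 4 in ET, 150 in TD and 165 in TT. In H3K27ac 4HT against EtOH the medians were 0.18 for proximal and 0.11 for distal regions, and after quantile normalization 0.02 and -0.03.

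**Figure D4:**
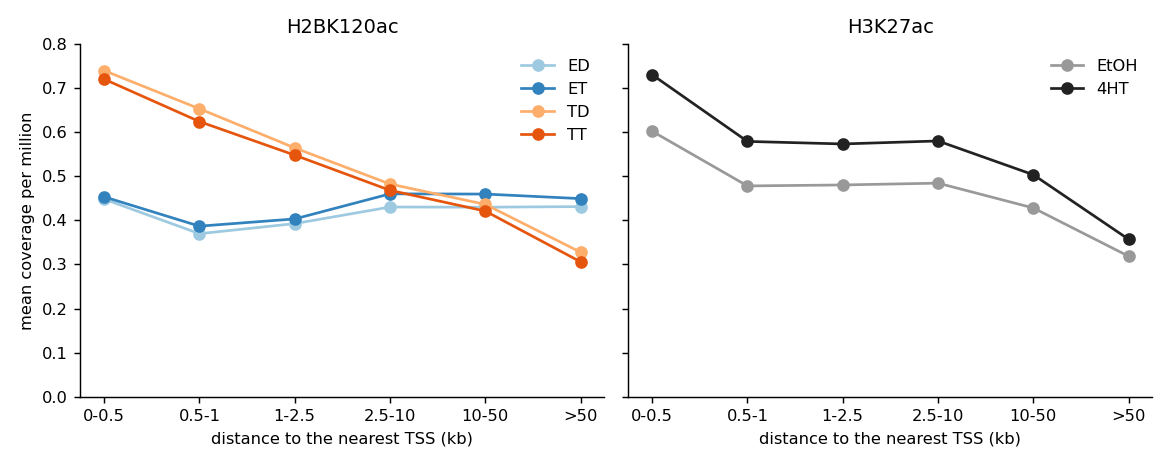
Mean coverage in CPM (vertical axis) of regions in 6 classes of distance to the nearest TSS (horizontal axis, kb), for the 4 H2BK120ac groups and the 2 H3K27ac groups. TD and TT fall from 0.740 and 0.720 within 500 bp to 0.328 and 0.306 beyond 50 kb, while ED and ET stay between 0.370 and 0.460.

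The regions that carried the most H2BK120ac coverage were largely different between the first letters. Of the 1000 highest regions, ED and ET shared 592 and TD and TT shared 731. ED and TD shared 87 and ET and TT shared 105, where chance gives 7.8. The 1000 highest H3K27ac regions of EtOH and 4HT shared 766. With the highest H3K27ac regions, ED shared 293 (EtOH) and 298 (4HT) and ET 294 and 322, where TD shared 138 and 149 and TT 146 and 160. Across marks the log2 folds were weakly related. At the 37431 regions kept in both tables, H3K27ac 4HT against EtOH and H2BK120ac TD against ED had a Spearman correlation of 0.05. It was 0.06 at the 2097 regions well covered in both. Of the regions past 2-fold in either, 52.3% of those kept and 61.6% of those well covered had the same sign, and with TT against ET in place of TD against ED 49.6% and 57.0%. No chance share was computed. At the well-covered regions both marks leaned upward, which alone raises the share. There 161 regions were at least 2-fold higher and 6 lower in H3K27ac, and 931 and 484 in TD against ED.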

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

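The test without each gene's highest region was set before its result was seen, and the tests on promoters, shared regions, enrichment strength and quantile normalization were chosen only after.

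The first-letter comparison had opposite directions for the second letters at 6 well-covered H2BK120ac regions, each at least 2-fold apart in both. The difference was not tested, and each group has 1 merged value. The log2 folds of TD against ED and of TT against ET were 1.76 and -2.63 inside Hmgxb4 near Tom1 (chromosome 8, 75026455 to 75026586), 1.86 and -1.29 near Bambi (chromosome 18, 3490655 to 3490961) and 1.28 and -1.10 inside Fn1 (chromosome 1, 71643304 to 71643419). They were 1.18 and -1.50 near Zscan2, 1.06 and -1.65 near Apela and 1.03 and -1.18 near Kcnv1.

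More H2BK120ac signal at p53 target genes in TD and TT was weighed against a general difference at promoters. Against promoters of like H3K27ac level in EtOH, the 9 listed genes with a promoter region had median log2 folds of 3.09 and 2.16, each at percentile 100 of matched lists, which argues against that explanation. Signal at 1 region per gene stays open. Without each gene's highest region the medians were 1.45 at percentile 99.05 and 1.09 at percentile 97.72, and the latter lies just past the upper end of the central 95% of random lists, the bound set beforehand. A criterion that this also exceed the spread over genes was added after the value was seen, and the value did not meet it. A response of these cells that the codes may stand for, a difference in handling and a mix-up of libraries or antibodies remain untested. With a mix-up, either TD and TT or ED and ET would not hold H2BK120ac. The labels give neither the codes' meaning nor a batch.

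The highest H2BK120ac regions differed between the groups coded E and T. Stronger enrichment of a shared set of regions would make the 1000 highest regions of ET at least as high in TD as in ED. That prediction holds only if these are marked regions. Their median log2 fold was -1.15 (bootstrap interval over regions -1.23 to -1.09), and that of the 1000 highest regions of TT was 2.43. If the regions of ET are in part background, stronger enrichment in TD would lower them too, so this decides nothing. Counting noise is argued against by the overlap within a first letter, at least 592 of 1000 regions, where across first letters it was at most 105. A batch that separates E from T and a larger share of background in ED and ET stay open, since the labels give no batch and the IgG columns were not used. ED and ET shared more of their 1000 highest regions with H3K27ac (293 to 322) than TD and TT did (138 to 160), where chance gives 7.8. This bears against highest regions of ED and ET set by evenly spread background alone. Such background hardly changes which regions rank highest, so its share stays open, as does background at open chromatin. Mean coverage within 500 bp of a TSS and beyond 50 kb was 0.448 and 0.431 in ED, and 0.453 and 0.449 in ET.

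H3K27ac values were higher in 4HT at strongly marked regions. A difference in signal over background between the columns and a widespread effect of FOXD3 depletion cannot be told apart, with 1 merged column per group. After quantile normalization 423 regions were at least 2-fold higher and 294 lower. This decides nothing, since the method removes a net excess whatever its source, and the simulated counting noise of 741 and 891 is overstated.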

How the results depend on the processing

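The pile-up minimums, the requirement of coverage in every group and the choice of regions by H3K27ac coverage were chosen after seeing the data, the other alternatives before the data were examined. The p53 target median stayed positive in TD against ED (1.44 to 2.67) and in TT against ET (1.14 to 1.96) under each alternative run. Median centring reversed the ET against ED medians of proximal and distal regions. Quantile normalization reversed these, the H3K27ac distal median and the H3K27ac cell cycle list median (-0.045 against 0.18). The smaller or more scattered list medians that changed sign included, with quantile normalization, Fox and Sox and mesendoderm in H3K27ac, naive pluripotency in TD against ED and p53 targets in TT against TD. With median centring they included WNT, mesendoderm, neuroectoderm and formative and primed in TD against ED. The cause was not tested, except that fewer or more regions enter under another filter or minimum. No paired analysis was possible because each group has 1 merged column, and the replicate block, leaving out replicates, limma with and without a trend, fits of only the groups compared and count tests on recovered reads were not run for the same reason. Depth limits most regions to pile-ups of a few fragments. In the values that follow, counts are regions at least 2-fold higher/lower, and medians are of TSS-proximal or distal regions.

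With the pseudocount at 0.25 of its value, the higher/lower counts were 1403/169 (H3K27ac 4HT against EtOH), 434/167 (ET against ED) and 226/749 (the interaction). The median log2 folds were 0.23 (H3K27ac 4HT against EtOH, proximal), 0.14 (H3K27ac 4HT against EtOH, distal), 0.42 (TD against ED, proximal), -0.15 (TD against ED, distal), 0.43 (TT against ET, proximal), -0.28 (TT against ET, distal), 0.0011 (ET against ED, proximal) and 0.0088 (TT against TD, proximal). The p53 target median was 2.67 (TD against ED). The Spearman correlation was 0.54 (agreement across second letters). With the pseudocount 4 times as large, the higher/lower counts were 281/14 (H3K27ac 4HT against EtOH), 33/6 (ET against ED), 14/28 (TT against TD) and 41/193 (the interaction). The median log2 folds were 0.10 (H3K27ac 4HT against EtOH, proximal), 0.062 (H3K27ac 4HT against EtOH, distal), 0.14 (TD against ED, proximal), -0.048 (TD against ED, distal), 0.14 (TT against ET, proximal), -0.091 (TT against ET, distal) and 0.00029 (ET against ED, proximal). The p53 target medians were 1.44 (TD against ED) and 1.14 (TT against ET). The Spearman correlation was 0.59 (agreement across second letters). With no filter, the higher/lower counts were 14571/8567 (H3K27ac 4HT against EtOH), 19514/28137 (TD against ED), 18922/28642 (TT against ET), 19050/18314 (ET against ED), 16974/17039 (TT against TD) and 24051/25270 (the interaction). The median log2 folds were 0.16 (H3K27ac 4HT against EtOH, proximal), 0.068 (TD against ED, proximal), -0.058 (TD against ED, distal), 0.11 (TT against ET, proximal), -0.053 (TT against ET, distal), 0 (ET against ED, proximal), 0 (ET against ED, distal) and 0 (TT against TD, proximal). The Spearman correlation was 0.31 (agreement across second letters) and 0.032 (agreement across marks). With regions above the median region, the higher/lower counts were 3916/1843 (H3K27ac 4HT against EtOH), 11625/14348 (TD against ED), 10764/15068 (TT against ET), 8031/7023 (ET against ED), 8379/8737 (TT against TD) and 10541/12279 (the interaction). The median log2 folds were 0.21 (TD against ED, proximal), -0.12 (TD against ED, distal), 0.23 (TT against ET, proximal) and 0.00070 (ET against ED, distal). The Spearman correlation was 0.46 (agreement across second letters). With median-centred values, the median log2 folds were 0.12 (H3K27ac 4HT against EtOH, proximal), 0.048 (H3K27ac 4HT against EtOH, distal), 0.38 (TD against ED, proximal), -0.034 (TD against ED, distal), 0.44 (TT against ET, proximal), -0.063 (TT against ET, distal), -0.049 (ET against ED, proximal), -0.032 (ET against ED, distal), 0.020 (TT against TD, proximal) and 0.014 (TT against TD, distal). With quantile normalization, the higher/lower counts were 423/294 (H3K27ac 4HT against EtOH), 321/181 (ET against ED), 61/67 (TT against TD) and 241/410 (the interaction). The median log2 folds were 0.017 (H3K27ac 4HT against EtOH, proximal), -0.030 (H3K27ac 4HT against EtOH, distal), 0.34 (TD against ED, proximal), -0.080 (TD against ED, distal), 0.42 (TT against ET, proximal), -0.10 (TT against ET, distal), -0.011 (ET against ED, proximal) and -0.011 (ET against ED, distal). The p53 target median was 0.19 (H3K27ac 4HT against EtOH). With proximal taken as 2.5 kb, the median log2 folds were -0.13 (TD against ED, distal) and -0.22 (TT against ET, distal). With a minimum of 3 fragments, the higher/lower counts were 1984/380 (H3K27ac 4HT against EtOH), 3154/1534 (TD against ED), 2726/1811 (TT against ET), 730/344 (ET against ED), 287/530 (TT against TD) and 521/1391 (the interaction). With a minimum of 10 fragments, the higher/lower counts were 370/8 (H3K27ac 4HT against EtOH), 372/62 (TD against ED), 344/63 (TT against ET), 67/10 (ET against ED), 8/14 (TT against TD) and 18/118 (the interaction). With coverage in every group required, the higher/lower counts were 209/66 (ET against ED). The median log2 folds were 0.25 (TD against ED, proximal), -0.058 (TD against ED, distal), 0.26 (TT against ET, proximal), -0.10 (TT against ET, distal) and 0.0056 (TT against TD, distal). At regions chosen by H3K27ac coverage, the higher/lower counts were 2795/2902 (TD against ED), 2386/3328 (TT against ET), 1184/792 (ET against ED), 950/1228 (TT against TD) and 1449/2360 (the interaction).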

Other observations

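All genes in this part were chosen after their values were seen.

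Outside the fixed lists, Rps27l and Fas, both known targets of p53, had more H2BK120ac signal in TD and TT. The 1 kept region of Rps27l had 9.67 in TD and 8.82 in TT, against 0.552 in ED and 1.26 in ET. The 1 kept region of Fas had 2.52 and 3.15, and had no coverage in ED or ET. H3K27ac at Rps27l was 2.92 in 4HT and 2.30 in EtOH, and at Fas 0.349 and 0.246. Among the genes with the highest log2 folds in both first-letter comparisons, Mmrn2 had 21.6 in TD and 20.4 in TT against 1.05 in ED and 2.09 in ET, and Fbxw9 had 9.90 and 8.48 against 0.398 and 0.445. Among those with the lowest, Tmprss11d had 0.728 in TT against 5.80 in ET, and Trim43b had no coverage in TD or TT against 2.68 in ED and 1.78 in ET. H3K27ac at Tmprss11d was 5.75 in 4HT and 5.25 in EtOH.

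A few regions had high coverage in every group. The region at chromosome 8, 19784839 to 19784972, nearest to Defb7, ran from 16.7 in ET to 63.1 in H3K27ac 4HT. The region at chromosome 1, 24613019 to 24613216, nearest to Col19a1, ran from 8.99 in TT to 18.5 in H3K27ac EtOH.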
